A study of Rattus norvegicus with 3 samples.

How the data were processed

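Total RNA of 3 samples of rat iPS F65 cells (Cy3) and of mix1, a mixture of rat bone marrow cells and primary ear fibroblasts (Cy5), was hybridised to 3 Agilent 2-colour arrays, per the labels. The dye orientation was the same on every array, with no dye swap, and the 3 arrays shared 1 slide and 1 scan, so no batch could be tested. Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 9.5.3.1. They hold mean spot and local background intensity values per channel, which carry no normalization, and processed signals, which the software had background-subtracted and dye-normalized within each array by a linear and LOWESS scaling. The log10 ratio column of red over green was made from those processed signals, per the file headers, and was not used here. The deposited log2 values of the series matrix matched the mean log2 ratio of green over red processed signals for each of the 41012 probes, with a largest difference of 3.1e-06, so their direction is iPS F65 over mix1 and they were not centred further. Their medians were 0.00, -0.01 and -0.06 on the arrays of replicates 1, 2 and 3.

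Each array held 45018 spots, of which 43379 measured genes. Mean signals were corrected with limma's normexp method with an offset of 50, using the median local background, and normalised within each array by loess with control spots at weight 0. Ratios were then turned to log2 of iPS F65 over mix1. Control spots and spots with an outlier flag (204 to 213 per array) were left out, and no spot was saturated. Local backgrounds flagged as uneven (681 to 789 spots per array) were replaced by the array's median background before normexp. This step was not in the first plan and was added after the results of the planned correction had been seen. With the backgrounds as given, 7, 11 and 1 spots of the 3 arrays had a signal below their own local background, which reached 65274 against a median of 42 on the array of replicate 1. The fitted mean background in Cy3 was then -1162 on the array of replicate 1 and -1053 on that of replicate 2, against 20.7 on that of replicate 3. With all flagged backgrounds replaced it was 14.5, 16.9 and 20.7. The effect of the few spots below their own background was not tested apart. Leaving the flagged spots out altogether was tried next, and was set aside because the flag fell on bright spots such as those of collagen genes, with a median brighter-channel signal of 4096 to 4745. The planned correction called 2344 genes higher and 2084 lower, and leaving the spots out called 3891 and 5468. The planned correction became an alternative only when the reported one replaced it, and leaving the spots out was chosen after seeing the data.

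Spots of 1 probe were averaged. A probe was tested if it was well above background on all 3 arrays in Cy3 or on all 3 in Cy5, which held for 25801 of 41012 probes. A gene with several probes was represented by its brightest. Of 3261 genes with more than 1 tested probe, 8 had probes called in opposite directions. Probes were named through a table of RefSeq genes of a newer rat assembly, by accession (10802 probes), gene number (1215), symbol (5552) or a unique older name (3718). The remaining 19725 probes kept the file's name, and 19707 probes have only a provisional name. Naming by gene number was added when members of the lists were found without a match, before any test was run. Of the 21768 genes tested, 11459 have a gene symbol. Chromosome positions are those of the array files, whose genome build is not given in the sources used here.

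Mix1 is 1 control sample, so each gene's mean log2 ratio was tested against 0 with limma 3.58.1 (lmFit and eBayes, R 4.3.3), which leaves out the spread of the control. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 ratio of at least 1. Where a gene was not well above background on any array of a channel, the text gives a bound. The brighter channel's mean level after loess and Aquantile normalization was set against the dim channel's mean of, per array, the higher of its own level and the lowest level above background. The 28 gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists, and with an estimated correlation, fry and a rank version beside it. A list needed at least 3 measured genes. Choices of lists, tests, thresholds and the rule for named genes were made before the data were examined, apart from the background step above. The rule took the 8 largest and 8 smallest ratios among called genes above background in both channels on all arrays, the 5 largest bounds in each direction, for each list the 2 called members with the largest ratios in its main direction and 1 in the other, and 10 fixed genes (Pou5f1, Sox2, Nanog, Klf4, Myc, Col1a1, Thy1, Ptprc, Actb and Gapdh). Not every gene the rule takes is printed.

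The scripts were tested on simulated intensities for the real spots with a dye curve and noise. With 200 of 21795 genes changed, all 40 genes of each size at log2 ratios of -4, -2, 2 and 4 were called in the right direction, with median fitted ratios of -3.75, -1.92, 1.88 and 3.76. None of the 40 genes at -0.5 and none of the 21595 unchanged genes was called, which the 2-fold limit all but ensured at the small simulated noise. None of 20 lists of unchanged genes was called, and the 1 changed list was. The noise was independent between genes, and no uneven background was simulated. Neither the preset correlation nor the background step was therefore tested. When the ratios of the processed signals themselves served as the truth, many genes changed. All 6082 genes with a true change of at least 4-fold were called in the right direction. However, the whole processing, normexp and loess together, moved the fitted ratios by a median of -0.39. Of the called genes 42.7% were higher, against 55.6% of the genes with a true change of at least 2-fold. Spike-in spots were well above background in only 6 to 14 of 320 spots per array and channel, so they give no check of fold sizes.

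Alternatives were no background subtraction, a normexp offset of 10, median centring, processed signals, the series matrix, Aquantile normalization between arrays, no filter on dim probes, a filter on both channels, the median over a gene's probes, leaving out each replicate, a test against a 2-fold change, adjusted p alone and a 4-fold limit. Files were read and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.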

Results

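Gene expression was compared between rat induced pluripotent stem (iPS) cells of the line F65 and a mixture of adult rat cells. The mixture, named mix1, combined RNA of cultured bone marrow cells and primary ear fibroblasts. The iPS cells were grown on irradiated mouse embryonic fibroblasts as a feeder layer. Each of 3 iPS F65 samples was labelled with Cy3 and hybridised against mix1, labelled with Cy5, on its own 2-colour Agilent array, and the 3 arrays lay on 1 slide. The comparison asks which genes are higher or lower in the iPS cells than in the adult cells. Between 57.1% and 61.2% of the gene spots on an array were well above background in the iPS channel, and between 58.3% and 62.1% in the mix1 channel. The precision of every value is limited by the number of arrays, which is 3. iPS F65 was in Cy3 on every array, so an effect of the dyes cannot be separated from the difference between the cells. The labels do not say that the 3 samples came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical, and they leave out any spread of the adult cells, since mix1 is 1 control sample.

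Of 21768 genes measured above background in at least 1 of the channels, 3967 (18.2%) were higher and 5688 (26.1%) were lower in iPS F65, and 12113 were neither (limma, adjusted p under 0.05 and a change of at least 2-fold). Genes of connective tissue, macrophages and inflammatory secretion were among the largest decreases, while 20 of 35 measured genes of DNA replication, 19 of 33 of mitosis and 18 of 20 of homologous recombination repair, together with the stem cell factors Sox2 and Nr0b1 and the DNA methyltransferase Dnmt3b, were higher. Pluripotency genes as a list moved both ways. Of 22 measured from a list of 45, 8 were higher and 7 lower, among these Klf4 at a log2 ratio of -5.45. The list was not called (camera adjusted p = 0.617). With only probes well above background in both channels kept, which left 17230 genes, 32 were at least 16-fold higher and 598 at least 16-fold lower. The background correction as first planned, which was replaced after its results had been seen, gave 2344 genes higher and 2084 lower. With it 30 of 97 named genes lost their call, all in the same direction as reported. Those named in the text are Efhb, Pcdh17, Pax6, Ephx4, Sox3, Cdh2, Klf1, Ahsp, Gzmb, Eng, Tek, Epcam, Ocln, Hand2, Mixl1, Ncam1, Krt7, Cbx7, Aldoc, Psmb9, Igfbp5, Tnfrsf10b, Hoxa2, Hoxc10, Hoxa4, Nnat, Pou5f1, Thy1 and Ptprc. Each of the 9655 genes called had the same sign on all 3 arrays, which the 2-fold limit and the small spread between arrays all but ensured. The split between higher and lower depended on how the dyes were scaled. With loess, 41.1% of the called genes were higher. With each array's median set to 0 in place of loess, 6437 genes were higher and 4381 lower (59.5% higher), and with the scanner software's processed signals 6721 were higher and 5336 lower (55.7% higher). These settings moved the median log2 ratio of all genes from -0.08 to 0.33 and to 0.25. The processed signals also differ from the reported ones in their background subtraction, so their move is not due to dye scaling alone. The ratios below are those after loess, with that median of -0.08 not subtracted.

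**Figure D1:**
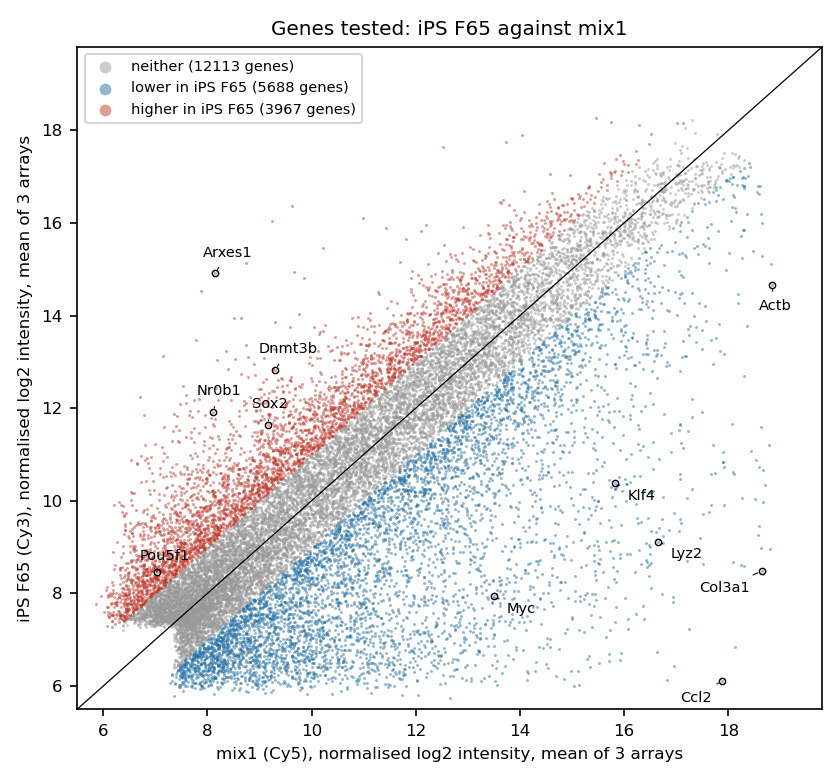
Each point is 1 gene, with its normalised log2 intensity in mix1 (Cy5) on the x axis and in iPS F65 (Cy3) on the y axis, both as means of 3 arrays, and the line marks equal levels. Red points are the 3967 genes called higher in iPS F65, blue points the 5688 called lower and grey points the 12113 called neither, and the blue points reach farther from the line than the red ones.

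The largest increases among named genes measured in both channels were those of Arxes1 and Hdgfl1. Arxes1 was higher by a log2 ratio of 6.76 ± 0.08 (SD, n = 3), which is 108-fold, and Hdgfl1 by 6.40 ± 0.08 (84.7-fold). They were followed by Filip1 (5.69), Alx1, a homeobox transcription factor of craniofacial development (5.44), Bex1 (5.11), Ccnb1ip1, a ligase that acts in meiotic recombination (4.85), Elavl2, an RNA-binding protein of neurons (4.63), and Slc7a3, a transporter of cationic amino acids (4.47). The largest adjusted p of these 8 genes was 7.11e-07, for Slc7a3. The probe of Arxes1 lies on chromosome X at positions 123326883 to 123326942 in the array's own coordinates, whose genome build is not given in the sources used here. Genes above background in iPS F65 but not well above background in mix1 have only a lower bound on their ratio, taken against the dimmest signals still above background. Efhb was at least 26.4-fold higher, Pcdh17 at least 17.0-fold, Pax6, a transcription factor of eye and brain development, at least 15.2-fold, and Ephx4 at least 14.2-fold. All bounds in the text were computed with the reported background correction and need not hold with the planned one. There the calls of these genes were lost, at log2 ratios of 2.97 for Efhb (adjusted p = 0.0684), 2.34 for Pcdh17 (0.0896), 2.26 for Pax6 (0.0928) and 2.12 for Ephx4 (0.0949). Such bounds held for 750 of the genes higher and 1375 of the genes lower in iPS F65, and they are open to dye bias. Calls and counts used the fitted ratios, so a gene counted as called can have a bound under 2-fold.

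The largest decreases measured in both channels were those of the collagen gene Col3a1, with a log2 ratio of -10.16 ± 0.02 (1145-fold), the growth arrest gene Gas1, with -10.03 ± 0.10 (1044-fold), and Mgp, which encodes matrix Gla protein, with -9.83 ± 0.05 (912-fold). Ccdc80 (-9.71), the small proteoglycan gene Dcn (-9.65), Ccn2, which encodes connective tissue growth factor (-9.63), the myosin light chain gene Myl9 (-9.40) and the metalloproteinase inhibitor Timp2 (-9.33) followed, and the largest adjusted p of these 8 was 2.03e-07. The probe of Col3a1 lies on chromosome 9 at positions 44318879 to 44318938. In the iPS channel 5 further genes with large decreases were not well above background. Grem1, an antagonist of bone morphogenetic proteins, was at least 2416-fold lower, the chemokine Ccl2 at least 2041-fold, the interleukin-33 receptor Il1rl1 at least 1073-fold, Ogn at least 978-fold and Gsta1, a glutathione transferase, at least 531-fold.

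**Figure D2:**
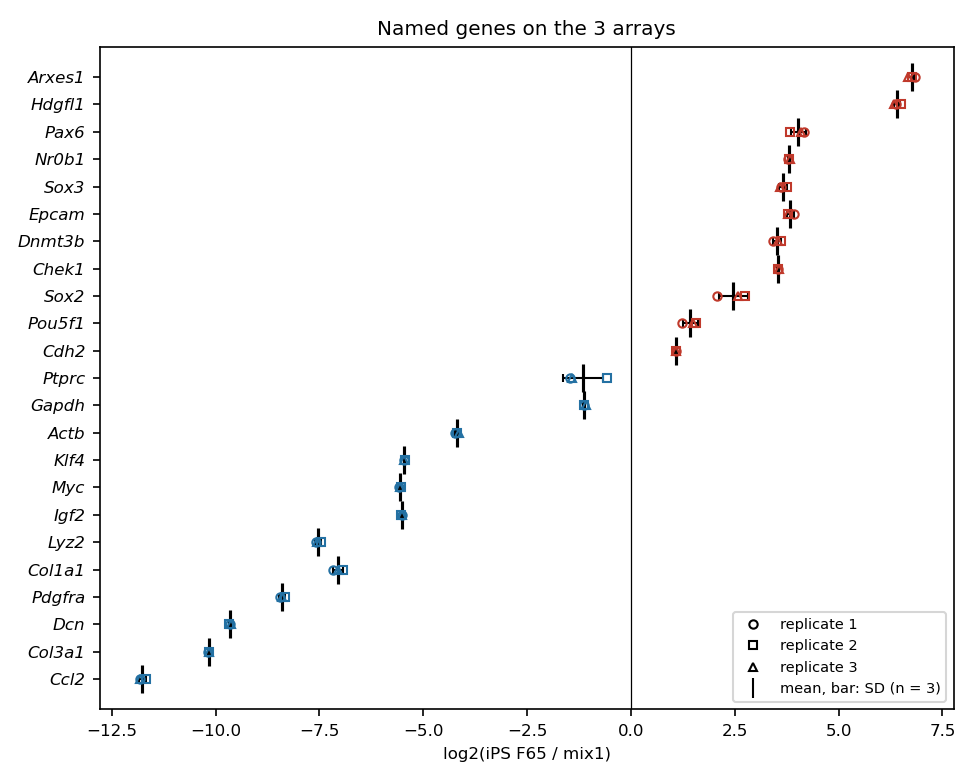
Log2 ratios of iPS F65 over mix1 (x axis) are shown for 23 named genes. Open symbols are the 3 arrays, red for genes called higher and blue for genes called lower, black ticks are the means and bars the SD (n = 3). Values are fitted ratios, also for Pax6, Epcam, Pou5f1 and Ccl2, which were dim in a whole channel and have only bounds. Arxes1 lies at 6.76 and Col3a1 at -10.16, and the arrays lie far closer to each other than to 0 for most genes, with Ptprc (SD 0.49) and Sox2 (SD 0.35) spread most.

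Gene lists were fixed before the data were examined. In all 28 lists, the counts adjusted over the list alone were the same as those adjusted over all genes tested. These counts could hardly differ, since 20859 of the 21768 genes had an adjusted p under 0.05 and the 2-fold limit set nearly all calls. The fibroblast and mesenchymal list fell almost as a whole. Of its 51 measured members, 50 were lower in iPS F65 (50 adjusted over the list alone) and 1 was higher, with a median log2 ratio of -6.92 (limma's camera, adjusted p = 2.4e-10; adjusted p = 0.556 with an estimated correlation). Besides Col3a1 and Dcn, the type I collagen gene Col1a1 was lower by -7.05 ± 0.12, and the surface marker Thy1 was at least 27.8-fold lower, with a fitted log2 ratio of -2.79 with the planned background correction. The exception was Cdh2, which encodes N-cadherin and was higher by 1.08 ± 0.01. This call was lost when the background model was fitted to all spots (0.95). Of 19 measured genes of the TGF-beta response, 16 were lower and none higher (median -4.47, adjusted p = 0.00266; adjusted p = 0.556 with an estimated correlation), and 2 were higher with median centring or processed signals. Ccn2 and the ligand gene Tgfb3 (-7.39 ± 0.07) led this list, which shares members with the fibroblast list, Ccn2 and Tgfbi among them. With a correlation between genes estimated from the 3 arrays in place of the preset one, no list kept its call. That version tests with only 2 residual degrees of freedom, so it could hardly call any list. The mitosis list lost its call at an estimated correlation of -0.0115, under the preset 0.01. The other called lists had estimates above the preset, from 0.0573 for the chromatin list to 0.412 for the myeloid list. If those estimates hold, the adjusted p of these lists at the preset are too small.

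Genes of macrophages and other myeloid cells were lower in all 25 measured cases, with a median of -5.49, or -5.02 with dim genes at their bounds (camera, adjusted p = 6.03e-06; adjusted p = 0.556 with an estimated correlation). The lysozyme gene Lyz2 was lower by -7.53 ± 0.06, and the protease gene Ctss was at least 114-fold lower. Ptprc, the pan-leukocyte surface marker CD45, had a smaller and less even ratio of -1.15 ± 0.49 (adjusted p = 0.00599) and was well above background in the iPS channel on 1 of 3 arrays. Its call was lost without replicate 1, where the change was just under 2-fold (adjusted p = 0.0304), and with the processed signals, where the ratio was -2.26. Of 21 measured genes of inflammatory secretion, 20 were lower and none higher, with a median of -5.87 (adjusted p = 8.79e-06; adjusted p = 0.556 with an estimated correlation). Ccl2 and the chemokine Cxcl2, at least 525-fold lower, led this list. Of 21 measured genes of interferon response and antigen presentation, 18 were lower and none higher, with a median of -2.75 (adjusted p = 0.000127; adjusted p = 0.556 with an estimated correlation), and 1 was higher with median centring. They included the antiviral membrane protein Ifitm3 (-7.47 ± 0.18) and the immunoproteasome subunit Psmb9, at least 64.6-fold lower but with a fitted log2 ratio of -3.84 (adjusted p = 0.0547) with the planned background correction. Lymphoid genes were mostly outside the measured range. Of 17 lymphoid genes with a probe 5 were measured, and of these Gzmb was lower, by at least 1.81-fold, a call that was lost without background subtraction (-0.98). Of 12 erythroid genes with a probe 5 were measured, with Klf1 higher (1.42 ± 0.00) and Ahsp lower (-1.09 ± 0.01), a call that was lost with median centring (-0.68) and processed signals (-0.85).

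Many genes of the cell cycle and of DNA repair were higher in iPS F65, and the rest of these lists were mostly neither higher nor lower. In the list of DNA replication and the G1 to S transition, 20 of 35 measured genes were higher and none lower, with a median log2 ratio of 1.25 (camera, adjusted p = 2.94e-07; adjusted p = 0.556 with an estimated correlation). Rfc4, a subunit of the clamp loader, was higher by 2.30 ± 0.03 and Orc1, a subunit of the origin recognition complex, by 2.18 ± 0.06. Of 33 measured mitotic genes, 19 were higher and none lower, with a median of 1.14 (adjusted p = 6.71e-07; adjusted p = 0.556 with an estimated correlation). They were led by Fbxo5, an inhibitor of the anaphase-promoting complex (2.52 ± 0.04), and the spindle checkpoint kinase Bub1b (2.46 ± 0.03). Of 20 measured genes of homologous recombination repair, 18 were higher and none lower, with a median of 1.52 (adjusted p = 6.03e-06; adjusted p = 0.556 with an estimated correlation). Among these, the checkpoint kinase Chek1 was higher by 3.54 ± 0.01 and Palb2, a partner of Brca2, by 2.12 ± 0.01. Of 26 measured regulators of chromatin and DNA methylation, 10 were higher and 1 lower, with a median of 0.86 (adjusted p = 0.00672; adjusted p = 0.556 with an estimated correlation). The de novo DNA methyltransferase Dnmt3b (3.52 ± 0.10) and the chromatin remodeller Chd7 (2.22 ± 0.02) were higher, and Cbx7, a Polycomb protein, was lower (-2.11 ± 0.05). With median centring 32 replication genes and 16 genes of the chromatin list were higher.

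The measured genes of pluripotency moved both ways. Of 45 genes in the list of naive and core pluripotency, 33 had a probe of that name and 22 were measured. Of the 22, 8 were higher, 7 were lower and 7 were neither. The list was not called (median 0.19, camera adjusted p = 0.617), which says nothing about its unmeasured members. Its mean was -0.19, opposite in sign to its median. The nuclear receptor Nr0b1 was higher by 3.81 ± 0.03 and Tdh, which encodes threonine dehydrogenase, by 2.88 ± 0.07. In the other direction, the Krüppel-like factors Klf4 (-5.45 ± 0.01) and Klf2 (-5.15) and the T-box factor Tbx3 (-4.80) were lower, as was the cytokine receptor subunit Il6st (-2.37). Klf2, Tbx3 and Il6st were named after their values were seen. No probe was named Nanog, Zfp42, Sall4, Tdgf1 or Prdm14, and Esrrb was not well above background in either channel on all arrays. Of the 4 reprogramming factors, Sox2 was higher by 2.47 ± 0.35 (adjusted p = 0.00012) and Pou5f1, which encodes Oct4, by at least 2.49-fold (adjusted p = 8.52e-05). Pou5f1 had a low signal, with a normalised log2 intensity of 8.46 in iPS F65 against 7.02 in mix1. Its call was lost when the background model was fitted to all spots (0.61, adjusted p = 0.244). Klf4 and Myc were lower by -5.45 ± 0.01 and -5.57 ± 0.03, both well above background in both channels. The median of the 4 was -2.01 (camera adjusted p = 0.758). Of 6 measured genes of the primed epiblast, Sox3 (3.66 ± 0.09) and Dnmt3b were higher and the claudin Cldn9 was 63.9-fold lower, with a camera adjusted p of 0.187 for the list. A dimmer probe of Sox3 was called in the opposite direction.

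**Figure D3:**
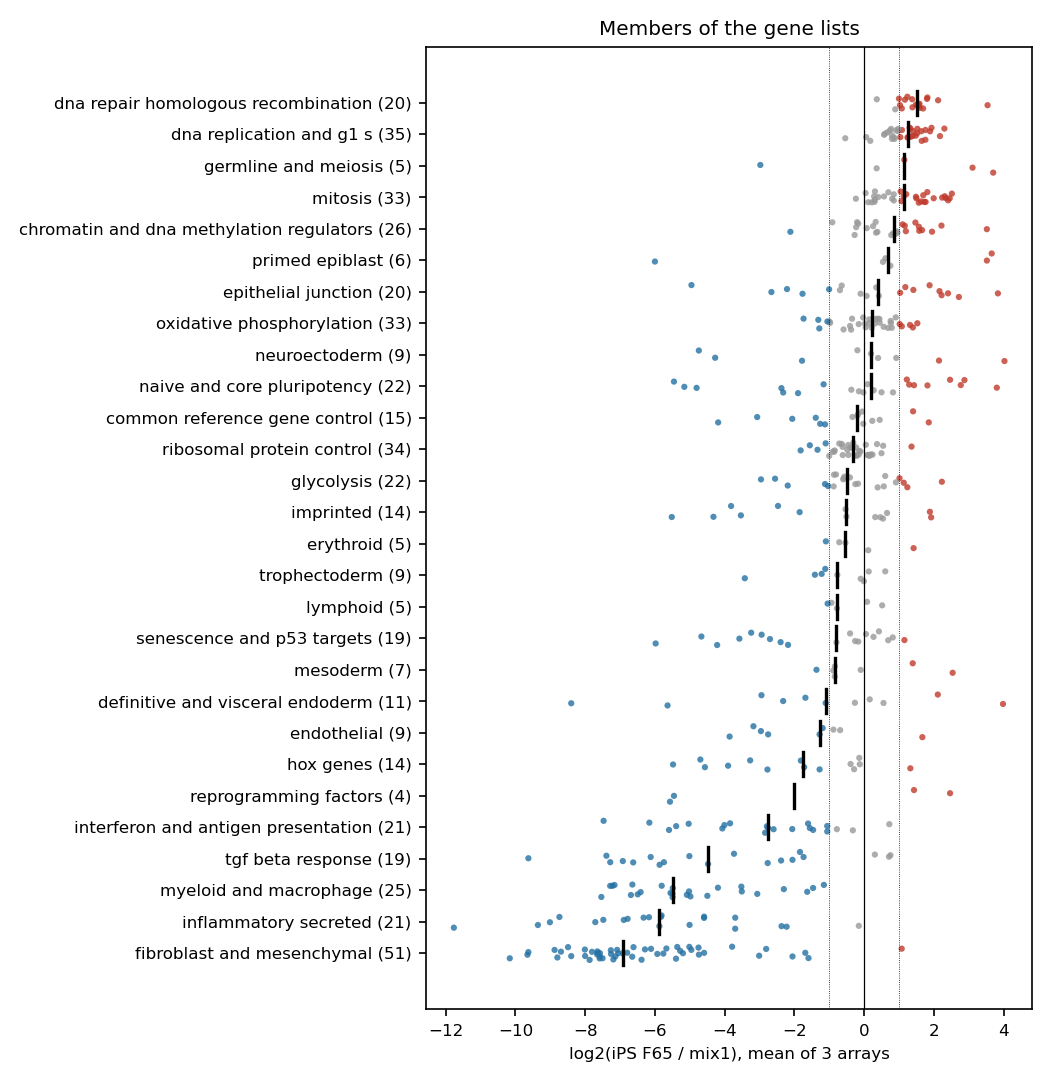
Each point is a measured member of a gene list, placed by its log2 ratio of iPS F65 over mix1 (x axis, mean of 3 arrays), with the number of measured members beside the list's name. Red points were called higher, blue points lower and grey points neither, black ticks are list medians and dotted lines mark a 2-fold change. Medians run from -6.92 for the fibroblast and mesenchymal list to 1.52 for homologous recombination repair.

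Markers of epithelia and of early lineages were mixed, and none of these lists was called. Of 20 measured genes of epithelial junctions, 9 were higher and 5 lower (median 0.39, camera adjusted p = 0.382). Krt19 and Crb3, counted among the 9, had bounds of only 1.22-fold and 1.40-fold. The adhesion molecule Epcam was at least 11.9-fold higher, with a fitted log2 ratio of 1.95 with the planned background correction, and the tight junction gene Ocln was higher by 2.72 ± 0.28, while Jup, which encodes plakoglobin, was lower by -4.95 ± 0.04. Of 11 measured endoderm genes, 2 were higher and 6 lower (median -1.10, adjusted p = 0.472). Afp, which encodes alpha-fetoprotein, was higher by 3.99 ± 0.08, and the receptor gene Pdgfra (-8.40 ± 0.06), which is also in the fibroblast list, and Dab2 (-5.64 ± 0.00) were lower. Of 7 measured mesoderm genes, Isl1 (2.54 ± 0.42) and Hand2 (1.40 ± 0.03) were higher and Mixl1 was lower (-1.36 ± 0.06), a call that was lost with median centring (-0.99). The mesoderm list had an adjusted p of 0.566, with a median of -0.84 (-0.51 with dim genes at their bounds) and a mean of -0.01. Of 9 measured neuroectoderm genes, 2, led by Pax6, were higher and 3, led by Msx1 (-4.74 ± 0.05) and Ncam1 (-4.27 ± 0.03), were lower. That list had a median of 0.20, a mean of -0.36 and an adjusted p of 0.758. Its median turned to -0.98 among genes well above background in both channels, and its test turned to the lower direction with median centring and processed signals, without a call. Of 9 measured trophectoderm genes, none was higher and 4 were lower (median -0.77, adjusted p = 0.329), among them Krt7, at least 7.14-fold, and Fgfr2 (-1.41 ± 0.01), whose call was lost with median centring (-0.71). With median centring and with processed signals 1 trophectoderm gene was higher, at list medians of -0.36 and -0.49. Of 25 germline and meiosis genes with a probe 5 were measured (median 1.15, adjusted p = 0.274). The median was 0.46 with dim genes at their bounds and 2.96 with processed signals. The homeobox gene Rhox5 (3.70 ± 0.12) and Piwil2, a Piwi protein of the germline (3.11 ± 0.12), were higher and Tdrd7 was lower (-2.98 ± 0.25).

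HOX genes, the transcription factors of body axis patterning, were lower in 9 of 14 measured cases and higher in 1, with a median of -1.77 (camera, adjusted p = 0.0233; adjusted p = 0.57 with an estimated correlation). Hoxa2 was at least 24.7-fold and Hoxc10 at least 16.7-fold lower, with fitted log2 ratios of -2.96 and -2.42 with the planned background correction, and Hoxa4 was higher by 1.33 ± 0.02. The call of this list was lost among genes well above background in both channels, where the median was -0.29 (adjusted p = 0.397). Of 9 measured endothelial genes, 6 were lower and 1 higher (median -1.28, adjusted p = 0.0509; adjusted p = 0.556 with an estimated correlation), and the list was called with median centring (adjusted p = 0.0249) and without replicate 3 (0.0372). Over the settings the median of this list ran from -2.84, with processed signals, to -0.20. The TGF-beta co-receptor Eng (-3.86 ± 0.07) and Egfl7 (-3.17 ± 0.02) were lower and the receptor Tek was at least 2.30-fold higher. Tie1, counted among the 6 lower, had a bound of only 1.59-fold. Of 19 measured genes of senescence and p53 targets, 9 were lower and 1 higher (median -0.79, mean -1.58, adjusted p = 0.173), and the list was called with median centring (adjusted p = 0.0396), where its median was only -0.11 and 3 genes were higher. Igfbp5 was at least 42.5-fold lower, though its fitted log2 ratio with the planned background correction was -3.48 (adjusted p = 0.0812), and the stress gene Gadd45a was lower by -4.66 ± 0.02, and the death receptor gene Tnfrsf10b was higher by 1.16 ± 0.06. Imprinted genes included 6 lower and 2 higher of 14 measured (median -0.52, adjusted p = 0.637), and the median turned to 0.04 without the filter on dim probes. With median centring 6 were lower and 5 higher, at a median of -0.07. The growth factor Igf2 was lower by -5.51 ± 0.01 and Nnat by -4.32 ± 0.08, and Snrpn was higher by 1.92 ± 0.02.

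Energy metabolism and control genes showed smaller and mixed changes. Of 22 measured glycolysis genes, 4 were higher and 5 lower (median -0.48, camera adjusted p = 0.472). With median centring and with processed signals 6 were higher and 3 lower, at medians of -0.07 and -0.14. The enzymes Aldoc (-2.96 ± 0.02) and Eno3 (-2.55 ± 0.02) were lower and the lactate dehydrogenase gene Ldhb was higher (2.23 ± 0.04). Of 33 measured genes of oxidative phosphorylation, 5 were higher and 4 lower (median 0.22, adjusted p = 0.19), with Cox5a (1.53 ± 0.03) and Ndufs1 (1.40 ± 0.01) higher and Cox6a1 lower (-1.73 ± 0.10). With median centring 12 of them were higher and 1 lower. Of 34 ribosomal protein genes, 29 were neither higher nor lower (median -0.32, adjusted p = 0.173), and this median turned to 0.04 with median centring and 0.06 with processed signals. Rplp1 (-1.82 ± 0.08) and Rps18 (-1.55 ± 0.07) were lower and Rps27a was higher (1.36 ± 0.08). Of 15 genes often used as references, 6 were lower and 2 higher (median -0.19, adjusted p = 0.332), and this median turned to 0.37 with median centring and 0.05 with processed signals. Actb, which encodes beta-actin, was lower by -4.18 ± 0.05, and Tfrc, which encodes the transferrin receptor, was higher by 1.86 ± 0.01. Gapdh was lower by -1.12 ± 0.02, a call that was lost with median centring (-0.84) and with processed signals (-0.73).

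The 3 arrays gave nearly the same ratios. Across genes, which are not independent replicates, Pearson's r of the log2 ratios was 0.998 for each of the 3 pairs of arrays. The median SD of a gene's 3 ratios was 0.03, and 90% of the genes had an SD of at most 0.10. The iPS channel differed between arrays by a median of 0.04 to 0.07 on the log2 scale, and the mix1 channel, where the same mixture was hybridised each time, by 0.05 to 0.08. In each of the 3 pairs of arrays the difference in the iPS channel was the smaller of these. The levels are those after loess and Aquantile normalization, which sets the mean levels of the spots to the same distribution on every array. The channels are thus coupled, and the differences do not show which sample varied less.

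**Figure D4:**
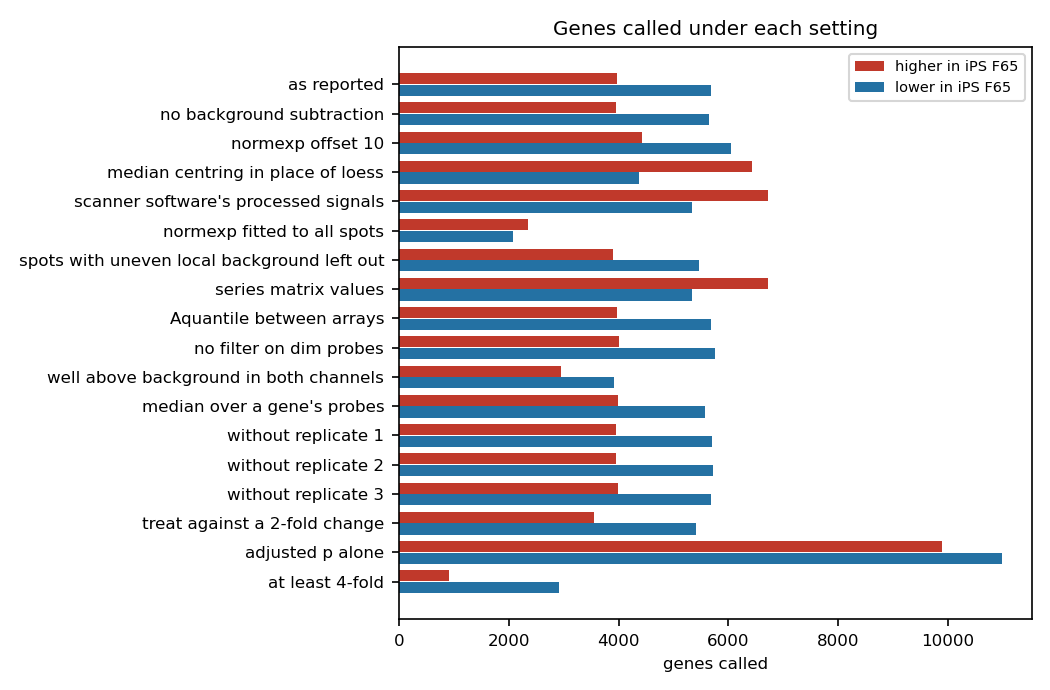
Bars give the number of genes called higher (red) and lower (blue) in iPS F65 under each setting, with the reported one at the top. Lower calls outnumber higher ones as reported (5688 against 3967), and higher calls outnumber lower ones with median centring (6437 against 4381) and processed signals (6721 against 5336).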

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

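Each array sets an iPS F65 sample against mix1, so the ratios are already paired, and with 1 group there was no further block to fit. Normexp fitted to all spots was the correction first planned, and the reported one replaced it after its results had been seen. Leaving out the spots with an uneven local background was also chosen after seeing the data, and the other alternatives were fixed before. Against the 3967 genes higher in iPS F65, median centring gave 6437, the processed signals and the series matrix 6721 each, normexp fitted to all spots 2344, adjusted p alone 9882 and a 4-fold limit 906. Against the 5688 genes lower, normexp fitted to all spots gave 2084, adjusted p alone 10977 and a 4-fold limit 2919. The last 2 limits change the counts by construction, and normexp fitted to all spots differs from the reported fit only in the uneven local backgrounds. With the processed ratios as the truth of a simulation with a dye curve, the reported processing moved the fitted ratios by a median of -0.39. It gave 42.7% higher among called genes, against 55.6% of the genes with a true change of at least 2-fold. The reported processing can therefore give a split like the reported 41.1% where processed signals give 55.7%. The simulation was not run without loess, so the part of loess in this is not known. Which scaling is nearer to the cells was not tested. The other alternatives gave counts within 1.5 times the reported ones, 11 for genes higher and 14 for genes lower. Of the 9655 called genes, 8328 were also called in the same direction with median centring, 8910 with processed signals and 4061 with normexp fitted to all spots, and none was opposite there. With a filter on both channels 6 genes were opposite, and with the uneven spots left out 1 was. Aquantile normalization leaves the ratios within an array as they are, so it tests nothing here.

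Between 9 and 12 of the 28 lists were called under the other scalings, filters and left-out replicates and with ranks, against 10 as reported, but 0 with an estimated correlation and 28 with fry, which does not compare a list with other genes. With an estimated correlation the adjusted p was 0.556 for the fibroblast, myeloid, replication, mitosis, homologous recombination, chromatin, interferon, inflammatory and TGF-beta lists and 0.57 for the HOX list. The HOX list also lost its call with normexp fitted to all spots (0.0535), with a filter on both channels (0.397) and with ranks (0.0611). The endothelial list, at 0.0509 as reported, was called without background subtraction (0.0491), with median centring (0.0249), processed signals or the series matrix (0.0145), uneven spots left out (0.0473) and ranks (0.0386), and ranged from 0.0372 without replicate 3 to 0.057 without replicate 1. The senescence list was called with median centring (0.0396) and ranks (0.0386). The losses with an estimated correlation came with only 2 residual degrees of freedom, and so say little about the lists. The cause of the other changes was not tested. With fry, the pluripotency list (0.000246) and the neuroectoderm list (6.59e-05) turned to lower, against higher with camera. The other lists that camera did not call had adjusted p with fry of 0.00101 (primed), 0.00412 (erythroid), 0.000161 (lymphoid), 4.67e-05 (endothelial, endoderm and imprinted), 0.00248 (epithelial), 0.000663 (mesoderm), 0.000341 (trophectoderm), 0.000569 (germline), 7.28e-05 (glycolysis), 0.000246 (oxidative phosphorylation), 4.08e-05 (senescence), 5.93e-05 (reprogramming factors), 0.000112 (ribosomal) and 0.000241 (reference genes).

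The mean correlation between arrays, 0.998 as reported, was 0.997 with an offset of 10, 0.993 with processed signals or the series matrix, 0.928 with normexp fitted to all spots, 0.996 without the filter on dim probes and 0.999 with the filter on both channels. Of 1323 comparisons for 97 named genes, 1281 kept the call, 42 lost it and 0 reversed it. These are not separate checks. Aquantile normalization left the ratios as they were, the series matrix all but repeated the processed signals, and the changes of filter drew on the same probe ratios. Calls were lost for 32 genes in all, and for 30 of them with the planned fit of normexp to all spots. Under the other alternatives 6 genes lost a call, namely Ahsp, Gzmb, Mixl1, Fgfr2, Ptprc and Gapdh. The filter on both channels left 74 of the 97 named genes. Signal over background limits 750 of the genes higher and 1375 of the genes lower to bounds, and 138 entries of the gene lists were not well above background in either channel.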

Other observations

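Genes were also grouped by the stem of their symbols, the letters before the first digit, into 116 families of at least 10 genes. A stem can also take in genes of another protein type, such as regulators named after a family. These families were formed after the data had been seen, so their tests are descriptive. By camera 16 families were higher and 10 lower in iPS F65. None was called with an estimated correlation (smallest adjusted p = 0.588), a version that again had only 2 residual degrees of freedom and could hardly call any family. Among nucleoporins, the proteins of the nuclear pore, 16 of 23 were higher and none lower, with a median log2 ratio of 1.40 (adjusted p = 2.26e-05; adjusted p = 0.588 with an estimated correlation). Of 51 genes with the stem Eif, the stem of translation initiation factors, 17 were higher and 3 lower (median 0.75, adjusted p = 0.000536, or 0.588 with an estimated correlation). The counts were 32 and 1 with median centring and 27 and 1 with processed signals. Of 18 Taf genes, which encode factors associated with the TATA-binding protein, 10 were higher and none lower (median 1.02). Of 28 genes of Ddx RNA helicases 14 were higher and none lower (median 1.01), and of 10 Utp genes of small ribosomal subunit assembly 8 were higher and none lower (median 1.32). Genes of mitochondrial ribosomal proteins were higher in 7 of 24 cases for the small subunit and 12 of 43 for the large one, 15 and 27 with median centring and 12 and 19 with processed signals. The Taf, Ddx, Utp and mitochondrial ribosome families each had an adjusted p of 0.588 with an estimated correlation.

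In the other direction, 26 of 28 collagen genes were lower and none higher, with a median of -5.83 (adjusted p = 1.67e-05; adjusted p = 0.588 with an estimated correlation). Of 13 Adamts genes of secreted metalloproteinases, 12 were lower and 1 higher (median -1.84), and of 14 matrix metalloproteinase genes 11 were lower and none higher (median -3.79), with 2 higher under median centring and 1 under processed signals. Of 11 Ccl chemokine genes 9 were lower (median -4.59), and of 10 Clec genes of C-type lectins 8 were lower (median -1.95). Genes with the stem Rab, that of GTPases which direct vesicle traffic, were lower in 26 of 55 cases and higher in 3. Their median was -0.89, or -0.32 with median centring, where 17 were lower. Of 11 clustered protocadherin genes of the beta cluster 9 were lower (median -1.39, or -2.80 with processed signals). With an estimated correlation the adjusted p was 0.616 for the matrix metalloproteinases and 0.588 for the other families of this paragraph. The medians of all the families named here kept their sign with median centring and with processed signals.

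In the 3 patterns that follow, the 2 tests on fibroblast genes and the check at the higher level were chosen after the results they measure had been seen. Large decreases far outnumbered large increases, with 957 fitted ratios at least 16-fold lower in iPS F65 and 58 at least 16-fold higher. These counts were 765 and 103 with median centring, 1422 and 329 with processed signals and 378 and 16 with the planned background correction. The scaling between the dyes was argued against as the whole cause, since the lowest ratio of these counts under median centring, processed signals and the series matrix was 4.32. A narrower range at the dim end of Cy5 was also argued against, by genes with a log2 level of at least 12 in their brighter channel. Of these, 722 of 4126 (17.5%) brighter in mix1 were at least 16-fold apart. Among those brighter in iPS F65 it was 37 of 3358 (1.10%), a ratio of 15.9. At a level of at least 14, a 16-fold gap ends at least 2.69 above the floor of either channel, and the ratio was 22.6. With the log2 ratios of median centring and of processed signals it was 24.4 and 21.5. For these 2 settings the genes were still picked by their reported levels, so the room above the floors was not measured. A dye effect on single genes stays open without a dye swap, and that genes special to the adult cells are more abundant there is a biological explanation that was not tested.

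Fibroblast genes lay far below mix1 and were still well above background in the iPS channel for 39 of the 51 measured, with a median log2 ratio of -7.19 and a lowest value of -10.16. Rat cells like those of mix1, present at a single share in the iPS samples, would give these genes a common lowest ratio. The SD of their ratios, 2.38, decides nothing alone, since 9 genes lay over 4-fold above the median, as transcription in the iPS cells themselves would also give, but 3 genes lay over 4-fold below it at a median replicate SD of 0.04, which argues against such cells as the whole source of the typical gene's signal. RNA of the mouse feeder fibroblasts could also bind the rat probes, and 6 of 6 abundant fibroblast genes were well above background there, at log2 ratios of -7.05 (Col1a1), -8.49 (Col1a2), -10.16 (Col3a1), -7.87 (Fn1), -7.58 (Sparc) and -4.59 (Vim). That source cannot be told apart from transcription in the iPS cells, because the binding of mouse RNA to these probes was not measured. Signal in the iPS channel was not limited to fibroblast genes. The myeloid genes Cd68, Laptm5 and Lyz2 had log2 levels of 10.14, 9.84 and 9.12 there, above the floors of that channel. Their log2 ratios were -5.02, -5.49 and -7.53. They were picked here after their values were seen, and other myeloid genes, such as Ctss, were not well above background there. A source common to both lists was not tested.

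On chromosome 2 23.4%, on 14 23.0% and on 17 22.5% of genes were called higher in iPS F65, with adjusted p of 0.001, 0.007 and 0.01 in a one-sided permutation test over 21 chromosomes. Their probes had a median GC content of 41.7%, the lowest of any chromosome and shared with others, and these shares were not tested with an adjustment for GC content or under another scaling.

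X-linked genes were called higher in iPS F65 more often than autosomal genes, 247 of 779 (31.7%) against 3512 of 19832 (17.7%), with a one-sided permutation p of 1e-04, the smallest that 10000 permutations can give. The shares were 41.3% against 29.1% with median centring and 42.4% against 30.4% with processed signals, ratios of 1.42 and 1.40 in place of 1.79. The GC content of the probes, which correlated with the log2 ratio at r = -0.18 across genes, was argued against as the whole cause, since the ratio of shares was 1.79 after adjustment for it, and so were clusters of related genes, since the ratio was 1.54 with 1 gene per megabase (p = 0.001). A dose difference that shifts all X-linked genes alike was not settled, since the shifts at the lower quartile, median and upper quartile were 0.40, 0.28 and 0.54, and the upper exceeded the lower by 0.148 (95% bootstrap interval 0.00923 to 0.299), which is unequal but under the difference of 0.3 set beforehand to exclude it. The sex of the cells and the state of their X chromosomes may differ between iPS F65 and mix1, which was not tested.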
